A study of Homo sapiens with 11 samples.

How the data were processed

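Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 11 samples of human cell lines. HEC-1-B is an endometrial adenocarcinoma line and HEK-293T is an embryonic kidney line. Per the labels, the antibodies were against H3K27ac (2 samples), a histone mark of active promoters and enhancers, against CTCF (6 samples), the zinc-finger protein that shapes chromosome loops, and against Rad21 (3 samples), a subunit of the cohesin ring. Per the labels, the edited HEC-1-B lines carry a mouse enhancer element in the human protocadherin alpha cluster. The line mE1 carries HS5-1, the line mE2 carries HS5-1BL, and 2 further lines carry the same elements with their CTCF binding sites (CBSs) mutated. Every group held 1 library, so no difference here has a replicate check and no p-value is given.

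Each deposited file was a list of peaks for 1 sample with chromosome, start, end, peak name and 1 score per peak. Peak names showed a caller of the MACS family, and Bowtie version 1 with the build hg19 (GRCh37) came from the submitters' processing notes. The caller version, thresholds, input control and read filters are not given in the sources used here. The authors' score per peak ran from 50 to 3100 in each deposited list. That range is the one that early MACS versions write for −10 times the log10 of p, which no header or label states. The score was used only to rank or filter peaks within a list. Read counts were not analysed here, so the depth of each library is unknown. The number of peaks, their width and the covered length are given instead, and all 3 move with depth and with fragment length. A peak missing from a list may be one below the caller's threshold there. On chromosome 5 it may also be one listed at displaced coordinates, as set out below.

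Overlaps were counted with bedtools 2.31.1 in both directions, with at least 1 bp shared, and summarised with pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15. Shares of peaks carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. The share expected by chance came from 100 random placements of the other list within its chromosomes, with gaps in the assembly not excluded. Other pairs of lists from the same parental line served as the only measure of how far 2 libraries differ. The comparisons between groups, the window on chromosome 5 from 140 to 141 Mb and a set of alternatives were fixed before the data were examined, and tests chosen later are named in the closing section. The alternatives fixed in advance were 3 other definitions of overlap, 3 stricter or length-matched selections by score, and autosomes only.

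The lists of the 6 edited samples did not share 1 coordinate system with the wildtype list on chromosome 5. For each of these lists the displacement of peak centres from the wildtype list of the same antibody was measured. All pairs of centres within 5000 bp were taken. The most frequent difference was found with a sliding window of 60 bp. The median of the pairs within 300 bp of that difference was used. The median step was added after a first look at the displacements. Its 95% interval came from 1000 bootstrap draws of pairs. Comparisons were made with the coordinates as deposited, as planned, and again with this displacement subtracted from peaks past 140410000 on chromosome 5. The second version was chosen after seeing the data. Peaks from 140400000 to 140410000 are called the insertion zone, also set after seeing the data, and were not moved. The overlap and displacement code was tested on simulated data: in 3 simulations from the 33992 wildtype CTCF peaks the displacement was recovered within 2 bp and the shared percentage within 1.13 points.

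No annotation or genome of hg19 was used here, and the gene table at hand is on another build. The planned counts of promoters per gene list and the CTCF motif search were therefore not run, and the rule for naming items was applied to peaks by position rather than by gene. That rule took the sites in the window that were missing from a list, the 10 highest-scored unshared peaks per cell line and the 5 highest-scored unshared peaks per direction for each edited line. The intervals called alpha, beta and gamma below rest on general knowledge of where these gene clusters lie in hg19, and the insertion zone lies just past the interval called alpha here. Start coordinates are 1-based. In the window, peaks of 1 antibody that overlapped were merged into sites, and each list was scored for having a peak at each site.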

Results

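The 11 peak lists ranged from 19978 to 53245 peaks. For CTCF, wildtype HEC-1-B cells had 33992 peaks, HEK-293T cells 53245, mE1 31399, the mE1 line with mutated CBSs 34174, mE2 32093 and the mE2 line with mutated CBSs 30626. For Rad21, wildtype HEC-1-B had 27975 peaks, mE1 39770 and mE2 33766. For H3K27ac, HEC-1-B had 19978 peaks covering 56.0 Mb and HEK-293T 22741 peaks covering 40.4 Mb. Median widths were 2481 and 1603 bp for these H3K27ac lists and 940, 616 and 634 bp for Rad21 in wildtype, mE1 and mE2. The CTCF lists had median widths of 641 bp (wildtype HEC-1-B), 643 bp (HEK-293T), 593 bp (mE1) and 650 bp (mE2 with mutated CBSs), against 376 bp in the mE1 line with mutated CBSs and 371 bp in mE2. The differences below rest on 1 library per group, with no replicates.

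The first question was whether the acetylated regions and CTCF sites differed between the 2 cell lines. At the protocadherin clusters, which encode neuronal cell-adhesion proteins, H3K27ac differed by interval. In the alpha interval (140.16 to 140.40 Mb) HEC-1-B had 4 H3K27ac peaks and HEK-293T had 0. They lay at 140207158 to 140208356, 140305766 to 140306959, 140345084 to 140346970 and 140380271 to 140385086. A further HEC-1-B peak at 140418722 to 140421175 overlapped a pair of CTCF peaks, the position that general knowledge gives to the human HS5-1 enhancer, and HEK-293T had none there. In the gamma interval (140.65 to 140.90 Mb) 1 H3K27ac peak was shared and 4 were listed in HEK-293T alone, at 140762218, 140855237, 140864257 and 140874274. Their score percentiles within the HEK-293T list were 0.328, 43.8, 30.2 and 25.7, the first close to the lowest score of the list. The 4 alpha peaks had percentiles of 42.7, 22.6, 66.2 and 79.9 within the HEC-1-B list. Neither line had an H3K27ac peak in the beta interval (140.43 to 140.65 Mb). In the part of the window before 140.16 Mb, 7 of the 8 acetylated sites were found in both lines. Past 140.90 Mb only 1 of 4 was, with 2 in HEC-1-B alone and 1 in HEK-293T alone. Acetylated sites of 1 line alone were thus not confined to the intervals of the gene clusters.

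The longer CTCF list of HEK-293T had more sites in the window than that of HEC-1-B. Over the 1 Mb window 35 CTCF sites were present in both wildtype lists, 30 in HEK-293T and not in wildtype HEC-1-B, and 1 in wildtype HEC-1-B and not in HEK-293T. These counts depend on list length and were not repeated at 1 length. At some shared sites the HEK-293T peak ranked past 33992, the length of the wildtype HEC-1-B list, as at 140014577 (rank 40289) and 140254747 (rank 50792). The same held for some sites of HEK-293T alone, as at 140092131 (rank 34799). The site of HEC-1-B missing from the full HEK-293T list, at 140206965 to 140208674, overlapped the acetylated HEC-1-B peak starting at 140207158. It was listed in each of the 5 HEC-1-B CTCF lists and in each of the 3 Rad21 lists. Of the 30 sites of HEK-293T, 7 lay in the alpha, 9 in the beta and 13 in the gamma interval, and 23 of the 30 were in no HEC-1-B list, edited lines included. Both lines had the CTCF pair at the HS5-1 position (140419708 to 140420562 and 140420663 to 140421430 in wildtype HEC-1-B), with H3K27ac in HEC-1-B alone.

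**Figure D1:**
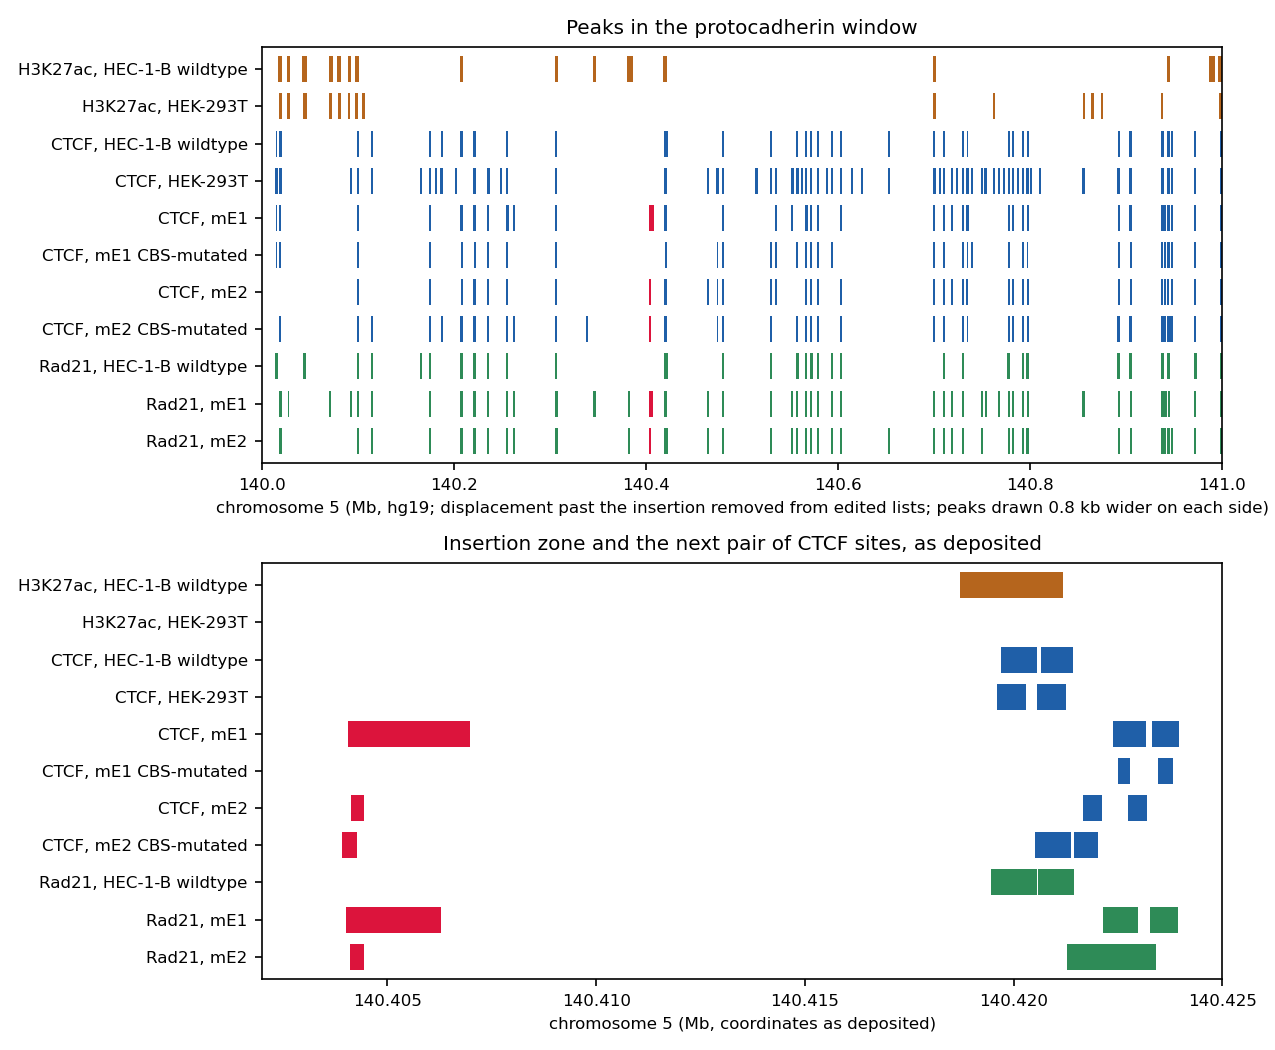
Peaks of the 11 lists on chromosome 5, in Mb on the x axis with 1 list per row (H3K27ac brown, CTCF blue, Rad21 green, insertion-zone peaks red). The upper panel shows the 1 Mb window with the displacement past the insertion removed from edited lists. The lower panel shows the insertion zone and the next pair of CTCF sites as deposited, where mE1, mE2 and the mE2 line with mutated CBSs have a red peak in the zone and the mE1 line with mutated CBSs has none.

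Across the genome CTCF sites were shared far more than acetylated regions. Of the HEC-1-B CTCF peaks, 92.7% (95% interval 92.4 to 93.0) met a HEK-293T peak, and 59.1% (58.6 to 59.5) of the longer HEK-293T list met a HEC-1-B peak. Random placement of the HEK-293T peaks gave 2.43% for the first share. For H3K27ac the shares were 54.7% (54.0 to 55.4) of HEC-1-B peaks and 49.8% (49.1 to 50.4) of HEK-293T peaks, and random placement of the HEK-293T peaks gave 3.90% for the first of these. Unshared H3K27ac peaks had lower scores within their own list, with a median percentile of 30.1 in HEC-1-B and 31.6 in HEK-293T, against 68.4 and 69.2 for shared peaks. The highest-scored HEC-1-B CTCF peak with no HEK-293T counterpart was at 157253884 to 157254456 on chromosome 7, ranked 4 in its list and present in the 4 other HEC-1-B lists. The highest-scored HEK-293T CTCF peak with no counterpart was at 186603251 to 186604298 on chromosome 2, ranked 96, and absent from the 4 edited lists too. For H3K27ac, the corresponding peaks were at 42397913 to 42400894 on chromosome 10 in HEC-1-B and at 244011945 to 244015203 on chromosome 1 in HEK-293T, each ranked 17 in its list.

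**Figure D2:**
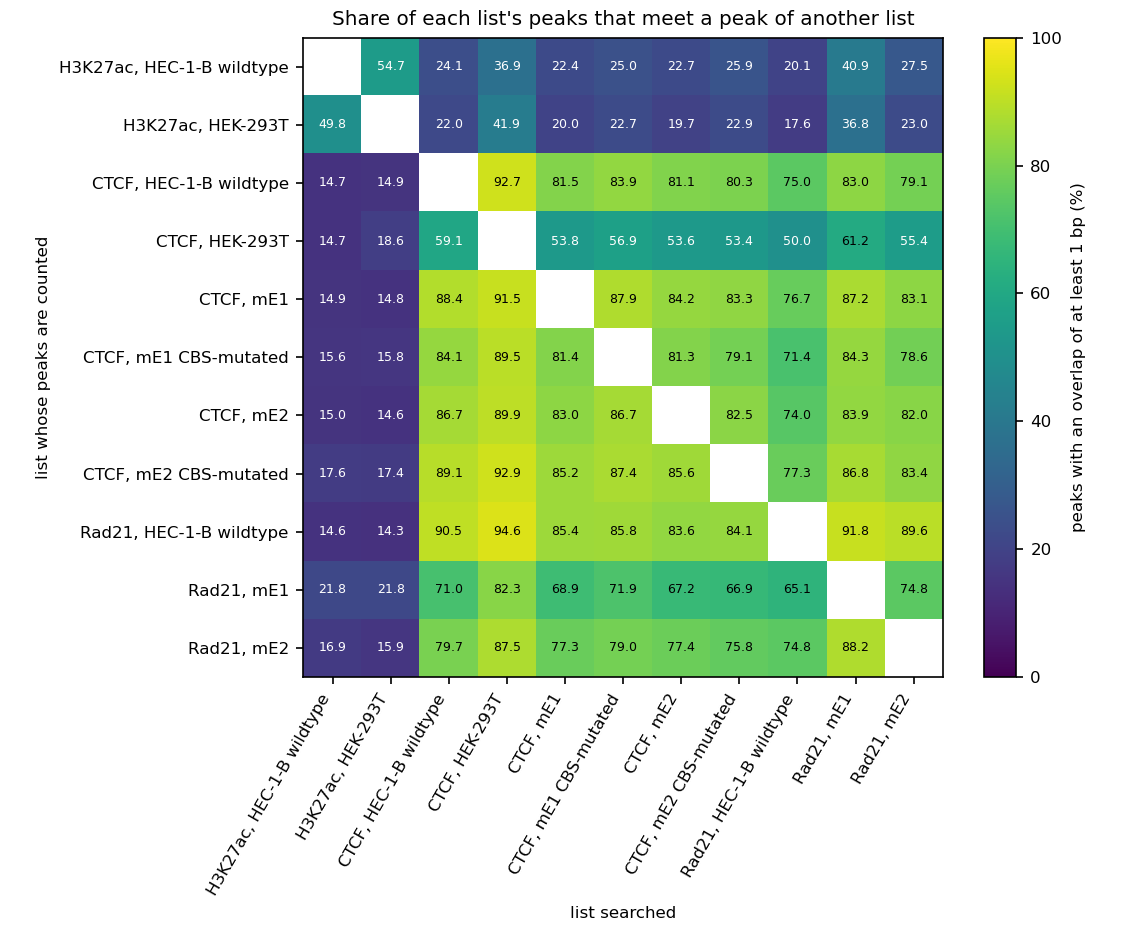
Share of each list's peaks (rows, in percent) that meet a peak of another list (columns) by at least 1 bp, coordinates as deposited. CTCF and Rad21 lists share most of their peaks, up to 94.6%, and the H3K27ac lists meet each other at 54.7% and 49.8%.

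The edited lines were compared with their parent to ask where CTCF and cohesin bind when a mouse enhancer element is added to the locus. On chromosome 5, peaks of the edited lines matched wildtype positions through the alpha interval up to the insertion zone and were displaced to higher coordinates past it to the end of the chromosome. The displacement was 2680 bp (95% interval 2673 to 2689) in the mE1 CTCF list and 2681 bp (2672 to 2689) in the mE1 Rad21 list. It was 1948 bp (1942 to 1956) and 1944 bp (1934 to 1954) in the mE2 CTCF and Rad21 lists. The lines with mutated CBSs were displaced by 2687 bp (2676 to 2694) for mE1 and 902 bp (894 to 911) for mE2. In the mE1 CTCF list, 92.0% of the 535 peaks past the insertion lay within 300 bp of a wildtype peak after this shift, and 0.935% did so without it. Before 140 Mb the displacement was at most 2 bp in each edited list, and on each of the 23 other chromosomes at most 23 bp.

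**Figure D3:**
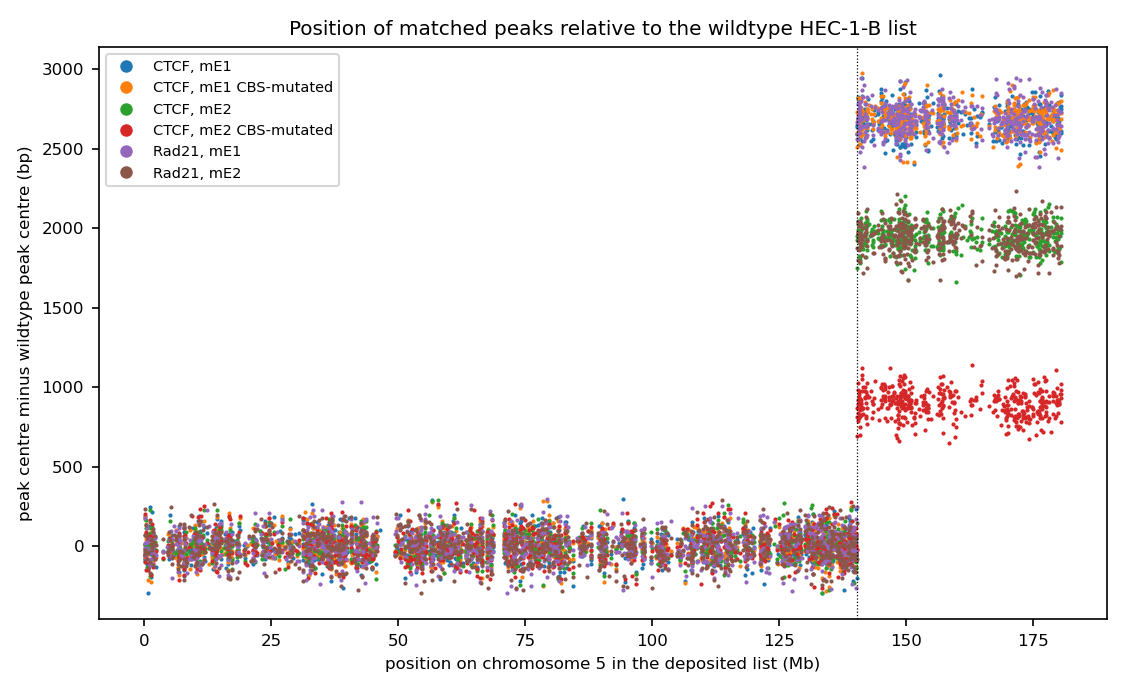
Centre of each matched peak minus the wildtype peak centre (y axis, bp) along chromosome 5 (x axis, Mb) for the 6 edited lists; points are peaks that lie within 300 bp of a wildtype peak before the insertion, or within 300 bp of one moved by the list's displacement past it. Past the dotted line the points sit near 2680 bp for the mE1 lines, 1948 bp for mE2 and 902 bp for the mE2 line with mutated CBSs.

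A CTCF peak appeared in the insertion zone of both lines with intact elements and in no wildtype list. In mE1 it spanned 140404054 to 140406981, 2928 bp, with a score of 668.69. It ranked 47 of 31399 in its list and 1 in the window. With the displacement removed it was the highest-scored mE1 CTCF peak in the genome without a wildtype counterpart. In mE2 the peak spanned 140404128 to 140404426, 299 bp, with a score of 413.34 and a rank of 910 of 32093. Rad21 had a peak at the same positions, from 140404010 to 140406275 in mE1 (rank 5301 of 39770) and from 140404111 to 140404443 in mE2 (rank 3100 of 33766). The wildtype Rad21, CTCF and H3K27ac lists of HEC-1-B had 0 peaks in the zone, as did both HEK-293T lists. If the edited lines were aligned to a chromosome 5 with the insert, a candidate weighed in the closing section, these peaks may lie on inserted sequence. Lists without the insert could then hold no peak there, so the lack of a wildtype counterpart is no test of the insert's effect.

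Mutating the CBSs of the inserted elements was compared with the intact insert of the same kind. The mE1 line with mutated CBSs had 0 CTCF peaks in the insertion zone, while its displacement differed from that of mE1 by 7 bp. The mE1 peak of the insertion zone was the highest-scored mE1 peak in the genome that was missing from the mutated line. The next such peaks, on chromosomes 22, 11, 4 and 1, ranked 95, 309, 339 and 356 in mE1, and each was listed in wildtype. High-scored peaks away from the insertion zone were thus missing from the mutated line too. The mE2 line with mutated CBSs had a peak at 140403914 to 140404276, with a score of 85.33 and a rank of 25421 of 30626. It shared 149 bp with the mE2 peak, and the centres lay 182 bp apart. This line was displaced by 1046 bp less than mE2, so positions past the start of the insert cannot be matched between them. Rad21 in the mutated lines was not analysed here.

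The human CTCF pair at the HS5-1 position was listed in each of the 5 HEC-1-B CTCF lists, edited or not. With coordinates as deposited, 7 CTCF sites of the window were common to these 5 lists. With the displacement removed, 25 of 47 sites were common. These included 5 sites of the alpha, 4 of the beta and 8 of the gamma interval. Of the window's CTCF sites, mE1 and wildtype shared 30, with 7 in mE1 alone and 6 in wildtype alone. The corresponding counts for mE2 were 29, 7 and 7. Between the mE1 line with mutated CBSs and mE1, 30 sites were shared, 5 were in the mutated line alone and 7 in mE1 alone. For mE2 these counts were 33, 6 and 3. For Rad21, 28 sites were shared by mE1 and wildtype, with 19 in mE1 alone and 3 in wildtype alone, and 28, 13 and 3 for mE2. These counts include the site of the insertion zone. It is among the sites of mE1 or mE2 alone against wildtype, and of mE1 alone against its mutated line. Between mE2 and its mutated line it counts as shared, although positions there cannot be matched. Both edited Rad21 lists were longer than the wildtype list, and genome-wide, too, only 66.2% of mE1 and 76.1% of mE2 Rad21 peaks met a wildtype peak with the displacement removed.

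Genome-wide, the CTCF list of an edited line overlapped the wildtype list about as much as it overlapped that of another edited line. Of mE1 CTCF peaks, 88.4% met a wildtype peak as deposited and 89.9% with the displacement removed. Of mE2 peaks, 86.7% and 88.2% did. Of wildtype peaks, 81.5% met an mE1 and 81.1% an mE2 peak as deposited. Between mutated and intact inserts, 81.4% of the peaks of the mE1 line with mutated CBSs met an mE1 peak in either version, and 85.6% of those of the mE2 line met an mE2 peak, or 87.1% with the displacement removed. With the displacement removed and the 2 directions averaged, the 4 pairs of an edited list with wildtype shared 85.4% to 86.4%, and the 6 pairs of edited lists 84.6% to 85.7%. Of the 4 planned contrasts above, only mE1 against wildtype compared lists of the same group of peak width. CTCF peaks of mE1 without a wildtype counterpart had a median score percentile of 11.8 within their list, and those of mE2 12.0. All 5 HEC-1-B lists shared 23725 of the wildtype CTCF peaks (69.8%), of which 98.6% were also in HEK-293T.

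As deposited, 4 of the 5 highest-scored mE1 CTCF peaks without a wildtype counterpart lay on chromosome 5 past the insertion, and 0 of 5 did once the displacement was removed. After the insertion-zone peak, the next of mE1 was at 102118945 to 102119360 on chromosome 1, ranked 5985, and it was present in the 4 other CTCF lists. For mE2 the highest was at 79186619 to 79186919 on chromosome 9, ranked 280 and also present in the 4 other lists, and the insertion-zone peak was number 4. For Rad21 in mE2 the insertion-zone peak was first. For Rad21 in mE1 the first was at 50764987 to 50766124 on chromosome 22, ranked 197. Between mutated and intact inserts, the first peak of the mE1 line with mutated CBSs missing from mE1 was at 14580817 to 14581032 on chromosome 16, ranked 104. For the mE2 line with mutated CBSs it was at 11733630 to 11734513 on chromosome 12, ranked 4113, and the first peak of mE2 missing from it was at 74283766 to 74284063 on chromosome 4, ranked 1370.

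In the other direction, mE2 lacked several of the highest-scored wildtype CTCF peaks. With the displacement removed, the 5 highest-scored wildtype CTCF peaks without an mE2 counterpart ranked 12, 40, 149, 162 and 179 in the wildtype list. They started at 1217592 on chromosome 2, 468841 on chromosome 6, 110824718 on chromosome 12, 155511278 on chromosome 2 and 34712940 on chromosome 1. Each was listed in mE1 and in both lines with mutated CBSs, and each was missing from HEK-293T. The wildtype Rad21 peak at 34712891 to 34713349 on chromosome 1, which covered the last of them, was also missing from mE2 and present in mE1. The Rad21 peak at 468581 to 469723 on chromosome 6 was missing from mE1 and mE2. For mE1, the highest-scored wildtype CTCF peak without a counterpart was at 39419502 to 39420333 on chromosome 6, ranked 3492 and present in the 4 other lists.

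Rad21 was compared with wildtype and with CTCF of the same line. Of wildtype Rad21 peaks, 91.8% (91.5 to 92.1) were found in mE1 and 89.6% (89.2 to 90.0) in mE2 as deposited. With the displacement removed these shares were 93.3% and 91.2%. In the other direction, as deposited, 65.1% (64.6 to 65.6) of mE1 and 74.8% (74.3 to 75.2) of mE2 Rad21 peaks were in wildtype. The wildtype list was the shortest. With each pair cut to 1 length by score, these shares were 82.7% and 84.9%. The share of Rad21 peaks at a CTCF peak of the same line was 90.5% (90.2 to 90.9) in wildtype, 68.9% (68.4 to 69.3) in mE1 and 77.4% (76.9 to 77.8) in mE2. Of CTCF peaks, 75.0% (74.5 to 75.5) had a Rad21 peak in wildtype, 87.2% (86.9 to 87.6) in mE1 and 82.0% (81.6 to 82.4) in mE2. The order of these shares followed the lengths of the Rad21 lists. With the Rad21 and CTCF lists of each line cut to the shorter length, the share of Rad21 peaks at CTCF was 83.2% in wildtype, 80.5% in mE1 and 80.0% in mE2. This cut shortened the CTCF list in wildtype, to 27975 peaks. In mE1 and mE2 it shortened the Rad21 list, to 31399 and 32093 peaks. The cut thus lowered the share in wildtype and raised it in mE1 and mE2, so these 3 values are not on 1 footing. With the 3 Rad21 lists cut to the length of the shortest by score, 9.48% of Rad21 peaks in wildtype, 14.7% in mE1 and 14.0% in mE2 had no CTCF peak of the same line, against 31.1% in mE1 and 22.6% in mE2 with the full lists. After the cut, 1.98% in wildtype, 3.25% in mE1 and 2.10% in mE2 had no CTCF peak in any list.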

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

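Both tests in this part were chosen after the widths and the overlaps between lists had been seen. The lines with mutated CBSs differed from those with intact inserts in opposite directions for the 2 kinds of element. The CTCF list of the mE1 line with mutated CBSs held 2775 more peaks than that of mE1, while the list of the mE2 line with mutated CBSs changed by -1467 peaks. The median peak width changed by -217 bp with mutation in mE1 and by 279 bp in mE2. Each value comes from 1 library, and the difference in the number of peaks was not tested.

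The 5 HEC-1-B CTCF lists fall into 2 classes of width, with wildtype, mE1 and the mE2 line with mutated CBSs from 593 to 650 bp and the mE1 line with mutated CBSs and mE2 at 376 and 371 bp. CBS mutation as the cause is argued against, since the 2 mutated lines lie 274 bp apart, in different classes. A library or batch difference cannot be told from the overlaps. Of the 10 splits of the lists into 3 and 2, the split by width had the largest mean overlap within parts minus between parts by 1 bp, at 0.734 points, but that measure itself depends on peak width, and by centres within 200 bp it was number 3, at 0.462 points against 0.766 for the first. The labels give no batch, so this and a difference between clones stay open.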

How the results depend on the processing

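The versions with the displacement removed were chosen after the result was seen and the other alternatives before. The cut of all Rad21 lists to the shortest, used outside this section, was not among the alternatives fixed in advance. Values are the share of peaks of the first-named list that meet the second, in percent, in the order H3K27ac of HEC-1-B in HEK-293T, CTCF of HEC-1-B in HEK-293T, CTCF of mE1 in wildtype, of mE2 in wildtype, of the mE1 line with mutated CBSs in mE1, of the mE2 line with mutated CBSs in mE2, Rad21 of mE1 in wildtype, Rad21 of mE2 in wildtype, and wildtype Rad21 at CTCF. The deposited values with 1 bp of overlap were 54.7, 92.7, 88.4, 86.7, 81.4, 85.6, 65.1, 74.8 and 90.5.

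Asking for overlap of 50% of the shorter peak, or keeping autosomes only, changed none of the 9 shares beyond its counting interval. Asking for 50% of both peaks gave 38.8, 86.9, 85.1, 56.5, 62.9, 52.5, 55.9, 66.7 and 77.9, with the largest falls where a list of narrow CTCF peaks met one of wide peaks. Asking for centres within 200 bp (1 kb for H3K27ac) gave 50.8, 88.6, 85.7, 84.2, 79.3, 82.7, 60.5, 69.5 and 84.4.

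Keeping the upper 50% of each list by score gave 64.7, 92.4, 82.8, 81.1, 76.3, 81.1, 64.3, 74.1 and 80.6, with only the second unchanged. Keeping the upper 50% of the first list and all of the second gave 77.3, 98.9, 97.9, 97.5, 98.5, 98.0, 92.5, 96.7 and 99.6. Unshared peaks were therefore mostly those of low score. Cutting both lists to the shorter length gave 52.9, 81.4, 85.8, 84.6, 85.8, 84.1, 82.7, 84.9 and 83.2. The Rad21 share of mE1 rose the most, and the CTCF share of HEC-1-B in HEK-293T fell by more than 10 points.

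Removing the displacement gave 89.9 and 88.2 for CTCF of mE1 and mE2 in wildtype, 87.1 for the mE2 line with mutated CBSs, and 66.2 and 76.1 for Rad21 of mE1 and mE2. The mE1 line with mutated CBSs stayed at 81.4, since both lists carried nearly the same displacement. In the protocadherin window 7 CTCF sites were common to the 5 HEC-1-B lists as deposited, 1 with the upper 50% of each list and 7 with lists cut to 1 length. With the displacement removed the counts were 25, 10 with the upper 50% and 23 with lists cut to 1 length. The promoter counts and the motif search were not run, and no library could be left out with 1 per group.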

Other observations

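The tests of displacement against another build and against the inserted sequence, and both tests on Rad21, were written before their results were seen, while the one on peak width was chosen after, as were the counts per 1 Mb window, of CTCF at H3K27ac and of sites missing from 1 list. The number of H3K27ac peaks differed between the cell lines in some 1 Mb windows, the 3 largest differences lying side by side on chromosome 6. HEK-293T had 42, 45 and 48 H3K27ac peaks in the windows of chromosome 6 starting at 26, 27 and 28 Mb, where HEC-1-B had 13, 10 and 10. By general knowledge the major histone gene cluster lies in this interval before 28 Mb, outside the window with the largest difference. The next were 41 peaks in HEK-293T and 19 in HEC-1-B from 1 to 2 Mb of chromosome 17, and 44 against 23 from 10 to 11 Mb of chromosome 19. In the other direction the largest differences were smaller. HEC-1-B had 20 peaks from 170 to 171 Mb of chromosome 3 and HEK-293T 5, and 23 against 8 from 5 to 6 Mb of chromosome 10. The number of peaks in a window depends on peak width too. H3K27ac peaks were wider in HEC-1-B, with a median of 2481 bp against 1603 bp, and the covered length per window was not compared. CTCF overlapped 24.1% of H3K27ac peaks in HEC-1-B (95% interval 23.5 to 24.7) and 41.9% in HEK-293T (41.3 to 42.6), whose CTCF list was the longer. In both lines CTCF was less frequent at the H3K27ac peaks of that line alone than at shared ones, at 20.2% against 27.3% in HEC-1-B and 36.6% against 47.3% in HEK-293T. The peaks of 1 line alone were also narrower, with median widths of 2106 against 2747 bp and 1315 against 1870 bp.

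With the displacement removed, 425 CTCF sites were in all 4 edited lists and missing from wildtype. The same count was 985 for sites missing from mE1 alone, 612 for the mE1 line with mutated CBSs, 868 for mE2 and 1159 for the mE2 line with mutated CBSs. Of the 425 sites, 364 were also in HEK-293T. Rad21 peaks of mE1 and mE2, with no wildtype Rad21 peak and no HEK-293T CTCF peak, were at 12 of them. One of the 12 lay within the protocadherin window, past the gene clusters, at 140940483 to 140940998 on chromosome 5 with the displacement removed, and had a score of 77.51 in mE1.

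Peaks past the insertion were displaced in each of the 6 edited lists. Another genome build is argued against, since the displacement on the 23 other chromosomes reached at most 23 bp. Differences in peak width or calling are argued against too, since the smallest displacement was 902 bp, while the median distance from the centre to the edge of a wildtype peak is 320.5 bp for CTCF and 470.0 bp for Rad21. Alignment to a chromosome 5 that carries each inserted sequence is a candidate explanation: the displacement in the first 9 Mb past the window and that in the last 20 Mb differed by at most 27 bp. On that hypothesis the displacement gives the net length added in each line, and why the mE2 line with mutated CBSs would have gained 1046 bp less than mE2 was not tested.

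More of the wildtype H3K27ac peaks had a Rad21 peak in the edited lines, with the displacement removed 41.4% in mE1 (95% interval 40.7 to 42.1) and 27.8% in mE2 (27.1 to 28.4), against 20.1% in wildtype (19.6 to 20.7), and as deposited 40.9% in mE1 and 27.5% in mE2. The share with a CTCF peak was 24.1% in wildtype, 22.6% in mE1, 22.9% in mE2, 25.2% in the mE1 line with mutated CBSs and 26.0% in the mE2 line with mutated CBSs. With the Rad21 lists cut to 1 length by score, 25.4% of the difference between mE1 and wildtype was left. The shares of H3K27ac peaks were then 25.5% in mE1, 21.0% in mE2 and 20.1% in wildtype. Most of the difference thus went with the lowest-scored peaks of the longer lists. The mE1 Rad21 peaks at H3K27ac and without CTCF of the same line fell from 4521 to 1415. A gain of low-scored peaks at acetylated sites would be removed by the same cut, so the cut cannot tell it from list length. Low-scored Rad21 peaks at acetylated sites without CTCF stay open as a source, since 91.9% of such mE1 peaks lay in the lower 50% of the list by score, but so did 89.6% of the mE1 peaks without CTCF away from H3K27ac, and 98.2% of such wildtype peaks at H3K27ac. At 1 length, 34.5% of the mE1 Rad21 peaks without a CTCF peak of the same line were at H3K27ac, against 19.3% in wildtype and 16.6% in mE2. Most of these peaks met a CTCF peak of another list. Only 909 of 4103 in mE1, 555 of 2651 in wildtype and 587 of 3915 in mE2 had none in any CTCF list. Of those, 62.9%, 41.3% and 38.7% were at H3K27ac. The source of the difference, with the 5.41 points left in mE1, and the effect of the edit itself stay open with 1 library per line.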
